A study of Rattus norvegicus with 35 samples.

How the data were processed

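The series holds amplicon libraries of the V3-V4 region of the bacterial 16S rRNA gene from rat colon and faeces. Per the labels' protocols, total DNA was extracted with the DNeasy PowerSoil Pro kit, the region was amplified with the primer pair 341F and 805R, and the libraries were read on an Illumina MiSeq. Per the submitters' processing notes, cutadapt, a trimmer of primer sequence, was used; its version, the tool that turned reads into features and any read filter are not given in the sources used here. The authors' deposited table holds raw read counts per feature, exported from a biom file per the file header, with no normalization. The lowest count above 0 in that table is 2, so features seen once in a library are absent from it, and detection here means at least 2 reads.

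Groups came from the tissue and treatment labels: control colon (n = 10), shocked colon (n = 8), control faeces (n = 9) and shocked faeces (n = 8). The labels number the libraries but do not say that each came from a separate animal, so p-values measure the spread between these libraries. Every library column was matched to a label by name. No library was left out of the main tests except where rarefaction required it. Read counts were compared between the 137 pairs of libraries of a same group, and no pair agreed within sampling noise (lowest chi-square per degree of freedom 9.82, median 38.3). The table pairs no feature with a taxon or sequence. The planned comparisons of genera, phyla, lists of bacteria and the ratio of Firmicutes to Bacteroidetes were therefore not made, and features were compared in place of genera. Folds are ratios of mean shares, except where they are said to come from geometric means or mean log2 shares.

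Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 by its quasi-likelihood F test on counts with TMM normalization, for features read in at least 25% of the libraries of the fit. Features with a Benjamini-Hochberg adjusted p under 0.05 were called. Footshock was tested within each compartment alone, compartment over all 35 libraries with treatment as a covariate, and the difference of the footshock responses as an interaction. The tested features held 80.9% of colon reads, 85.1% of faecal reads and 83.8% of all reads. Where a group had no reads of a feature, its fold is a lower bound against the group's mean floor, the floor of a library being 3 reads of its total. Floors and the 95% exact binomial (Clopper-Pearson) intervals of single libraries cover counting error only, since reads from PCR without molecular identifiers are not independent molecules.

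Diversity was computed after rarefaction to 1000 reads (mean of 100 draws), which kept 32 libraries and left out colon control 8 and colon shocked 12 and 17. Means were compared by exact permutation within a compartment and by 100000 resamples otherwise, all two-sided, with Benjamini-Hochberg adjustment over the 8 diversity comparisons. Composition was compared by permutational analysis of variance (adonis2 in vegan 2.7.1, 9999 permutations) on Bray-Curtis distances of read shares. Figures were drawn with matplotlib 3.10.9.

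The edgeR step was tested on simulated counts with the real depths and feature means. For colon, with 95 features, it called 64.3% of features changed 64-fold, 31.4% of those changed 16-fold and 10.0% of those changed 4-fold, and 1.89% of unchanged features. In faeces, with 135 features, the shares were 42.9%, 35.7%, 4.29% and 0.702%. Between compartments, with 127 features, they were 80.0%, 52.9%, 11.4% and 1.51%, and for the interaction 38.6%, 14.3%, 5.71% and 1.51%. Changes of 4-fold were thus mostly missed at these depths. False calls were also frequent among the calls. In colon, 14 calls fell on unchanged features, against 45, 22 and 7 on those changed 64-fold, 16-fold and 4-fold. The counts were 8 against 30, 25 and 3 in faeces, and 16 against 56, 37 and 8 between compartments. For the interaction they were 16 against 27, 10 and 4. In each simulated comparison, false calls were thus a larger share of the calls than the adjusted p threshold is meant to allow.

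Alternatives fixed before the data were examined were DESeq2 1.42.0 with poscounts size factors, TMMwsp normalization, library totals alone, limma 3.58.1 on centred log-ratios with 0.5 read added, no prevalence filter, a filter at 50%, 1 fit over all 4 groups, each library left out in turn, the library number as a block, other rarefaction depths and other distances. Added after seeing the data were thinning to 1000 reads, leaving out libraries under 1000 reads or both libraries numbered 1, and Fisher's exact test of detection. The rule for named features, also fixed beforehand, took those past the threshold with the largest fitted change in each direction. With no names in the table, at most 2 per direction and comparison are identified.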

Results

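Bacterial communities were profiled in the colon and in the faeces of rats by sequencing an amplified stretch of the bacterial 16S ribosomal RNA gene, and each library was summarised as read counts per sequence feature. Rats given footshocks, a procedure used to model post-traumatic stress disorder, were compared with control rats. The study asked whether this model is suited to research on interactions between gut and brain and on genes tied to irritable bowel syndrome. There were 10 libraries of control colon, 8 of shocked colon, 9 of control faeces and 8 of shocked faeces. Controls carried the numbers 1 to 10 and shocked animals the numbers 11 to 18 in the labels, and faecal number 9 was not analysed here. The libraries held 278978 reads in 1073 features. Features are identified here by a 32-character code because the files do not pair them with names of bacteria, so no genus or phylum is reported.

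Depth differed more between the sample types than between treatments. Colon libraries held 448 to 16155 reads (median 3097, n = 18) and faecal libraries 4703 to 24251 (median 10178, n = 17), a 3.58-fold difference of geometric means (two-sided permutation test, p = 3.0e-05). Control colon libraries averaged 6212 ± 5474 reads (SD, n = 10) and shocked colon libraries 2717 ± 2915 (SD, n = 8), a difference that did not pass the threshold (2.40-fold in geometric means, two-sided exact permutation test, p = 0.0777). Control faeces averaged 9934 ± 4342 reads (SD, n = 9) and shocked faeces 13214 ± 6731 (SD, n = 8; exact permutation test, p = 0.253). For a feature with no reads, the floor of 3 reads was 0.0124% of the deepest library and 0.670% of the shallowest.

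Most features were rare. Of the 1073 features, 571 were read in 1 library only and together held 2.72% of all reads, while 127 were read in at least 25% of the libraries and 3 in all 35. Colon libraries held 598 features and faecal libraries 846, with 371 features read in both. These shared features took 87.8% ± 9.45 (SD, n = 18) of colon reads and 92.1% ± 9.45 (SD, n = 17) of faecal reads. The 10 most abundant features of each library made up 51.4% ± 13.8 of reads in control colon (SD, n = 10), 53.2% ± 7.56 in shocked colon (SD, n = 8), 54.4% ± 8.38 in control faeces (SD, n = 9) and 47.2% ± 5.16 in shocked faeces (SD, n = 8).

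The first comparison asked whether footshock altered the bacteria of the colon. Of 95 features tested, 7 fell and 1 rose in shocked colon (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and each of the 8 had no reads at all in 1 of the 2 groups. Feature 932965d7ed2166402b521fea7a1029a4 was read in 5 of 8 shocked and 0 of 10 control libraries and averaged 1.21% ± 1.22 of reads in shocked colon (SD, n = 8), at least 10.9-fold higher than in controls against the mean of their floors of 3 reads per library (edgeR adjusted p = 0.00379). Feature 020f48a69f9bf40e54fbac885f94695a was read in 7 of 10 control libraries at 0.708% ± 0.637 of reads (SD, n = 10) and in 0 of 8 shocked libraries, at least 2.90-fold lower after footshock (edgeR adjusted p = 0.00901). Feature 2dfc021ab6895ae3b4c956d50052f17e was likewise read in 7 of 10 control libraries, at 0.680% ± 0.640 (SD, n = 10), and in 0 of 8 shocked libraries, at least 2.78-fold lower (edgeR adjusted p = 0.00901). These folds hold against floors of 3 reads and would be smaller against a floor that allows for 1 dropped read.

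The other 5 features that fell in shocked colon were minor members of the community. They were read in 5 or 6 of the 10 control libraries, averaged 0.207% to 0.337% of control reads, and were in none of the 8 shocked libraries. Floors of the shocked libraries averaged 0.244%, near those control means, so no fold is given for these 5. None of the 10 features with the highest mean share over all libraries passed the test. The feature with the highest mean share in colon made up 6.55% ± 3.49 of reads in controls (SD, n = 10) and 7.35% ± 1.87 in shocked colon (SD, n = 8). The count of 8 depended on the method, with 3 calls by DESeq2 (1 higher, 2 lower) and 2 by limma on centred log-ratios (2 higher, 0 lower). It was 0 in edgeR with a filter at 50% of libraries (3 of 40 at an unadjusted p under 0.05), in 1 edgeR fit over all 4 groups (18 of 127 unadjusted) and by Fisher's exact test of detection (13 of 95 unadjusted). It was 3 without the 3 libraries under 1000 reads, and 2 to 15 when 1 library at a time was left out. The Fisher test and the limit of 1000 reads were chosen after seeing the data.

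Colon communities of shocked and control rats did not separate in diversity. At an equal depth of 1000 reads, which leaves out control library 8 and shocked libraries 12 and 17, control colon held 106.2 ± 29.0 features (SD, n = 9) and shocked colon 77.1 ± 23.5 (SD, n = 6), a difference of -29.2 (two-sided exact permutation test, p = 0.0603, adjusted p = 0.121 over 8 diversity comparisons). The Shannon index, which rises with the number of features and the evenness of their shares, was 3.89 ± 0.365 in controls (SD, n = 9) and 3.64 ± 0.262 in shocked colon (SD, n = 6; exact permutation p = 0.172, adjusted p = 0.196). Treatment accounted for 8.37% of the variation in Bray-Curtis distance, a measure of unlike composition from 0 to 1 (permutational analysis of variance, p = 0.0951). With the Jaccard distance on presence and absence at 1000 reads, the share was 10.5% over the 15 libraries kept (permutation p = 0.0147). With the Aitchison distance on full counts with 0.5 read added, which does not equalise depth, it was 8.45% (permutation p = 0.026).

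**Figure D1:**
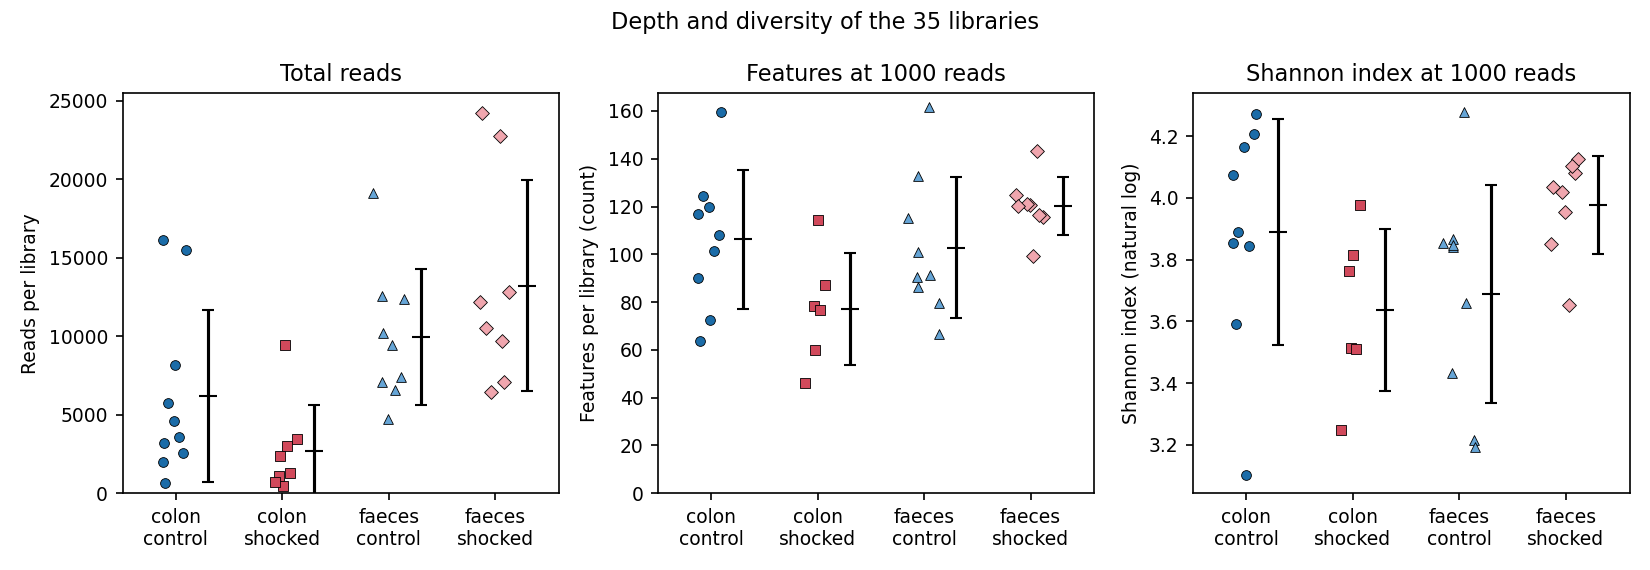
Total reads, number of features at 1000 reads and Shannon index at 1000 reads for each library by group; points are libraries and bars the mean ± SD, drawn from 0 reads upward in the first panel. Shocked colon averages 77.1 features against 106.2 in control colon, and shocked faeces 120.2 against 102.8 in control faeces, with overlapping libraries in both comparisons.

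The second comparison asked the same of faeces. Of 135 features tested, 2 fell and 0 rose in shocked faeces (edgeR, adjusted p under 0.05). Feature 141ddb34f78140905a869674af245c1b was read in 6 of 9 control libraries at 0.442% ± 0.393 of reads (SD, n = 9) and in 0 of 8 shocked libraries, at least 15.9-fold lower (edgeR adjusted p = 0.0334). This feature also fell in shocked colon, where it was read in 5 of 10 control and 0 of 8 shocked libraries (edgeR adjusted p = 0.0292). The call in colon was lost after thinning to 1000 reads (adjusted p = 0.0596) and without libraries under 1000 reads (adjusted p = 0.0891). Feature 2a45bceb7b5b7b43c02fb8b32cb55a09 was read in 5 of 9 control libraries at 0.392% ± 0.504 (SD, n = 9) and in 0 of 8 shocked libraries, at least 14.1-fold lower (edgeR adjusted p = 0.0369).

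The 3 features with the next smallest unadjusted p had log2 fold changes of 4.37, 4.37 and 1.60 in shocked faeces and each an edgeR adjusted p of 0.837. The feature at 1.60 was read in all 35 libraries and made up 2.60% ± 2.61 of reads in control faeces (SD, n = 9) and 7.31% ± 4.25 in shocked faeces (SD, n = 8). Of the 8 features called in colon, 2 could be tested in faeces, both had a lower fitted level there after footshock, and 1 was called, against 0.0563 expected for independent lists over the 71 features tested in both. That figure is too low if colon and faeces came from the same rats, which the labels do not say. Colon and faecal libraries of the same number were closer than shuffled ones (mean Bray-Curtis distance 0.658 against 0.684, permutation p = 0.0445). The 2 lists may thus not be independent. The count in faeces was 2 by DESeq2 and by limma on centred log-ratios as well, but 0 in edgeR with a filter at 50% of libraries (1 of 66 at an unadjusted p under 0.05), in edgeR after thinning every library to 1000 reads (8 of 117 unadjusted) and by Fisher's exact test (7 of 135 unadjusted), the last 2 chosen after seeing the data. It was 1 without faeces control 1, 3, 7 or 8 or faeces shocked 16, where feature 2a45bceb7b5b7b43c02fb8b32cb55a09 lost its call (edgeR adjusted p 0.0529 to 0.0621).

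Shocked faeces held 120.2 ± 12.1 features at 1000 reads (SD, n = 8) and control faeces 102.8 ± 29.4 (SD, n = 9; two-sided exact permutation test, p = 0.142, adjusted p = 0.189). The Shannon index was 3.98 ± 0.158 in shocked faeces (SD, n = 8) and 3.69 ± 0.352 in control faeces (SD, n = 9; exact permutation p = 0.0517, adjusted p = 0.121). Treatment accounted for 7.89% of the variation in Bray-Curtis distance among faecal libraries (permutation p = 0.0866). Without faeces control 1, a library unlike all the others, the share was 9.91% (permutation p = 0.0419). The Aitchison distance on full counts over all faecal libraries gave 7.64% (permutation p = 0.0355).

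**Figure D2:**
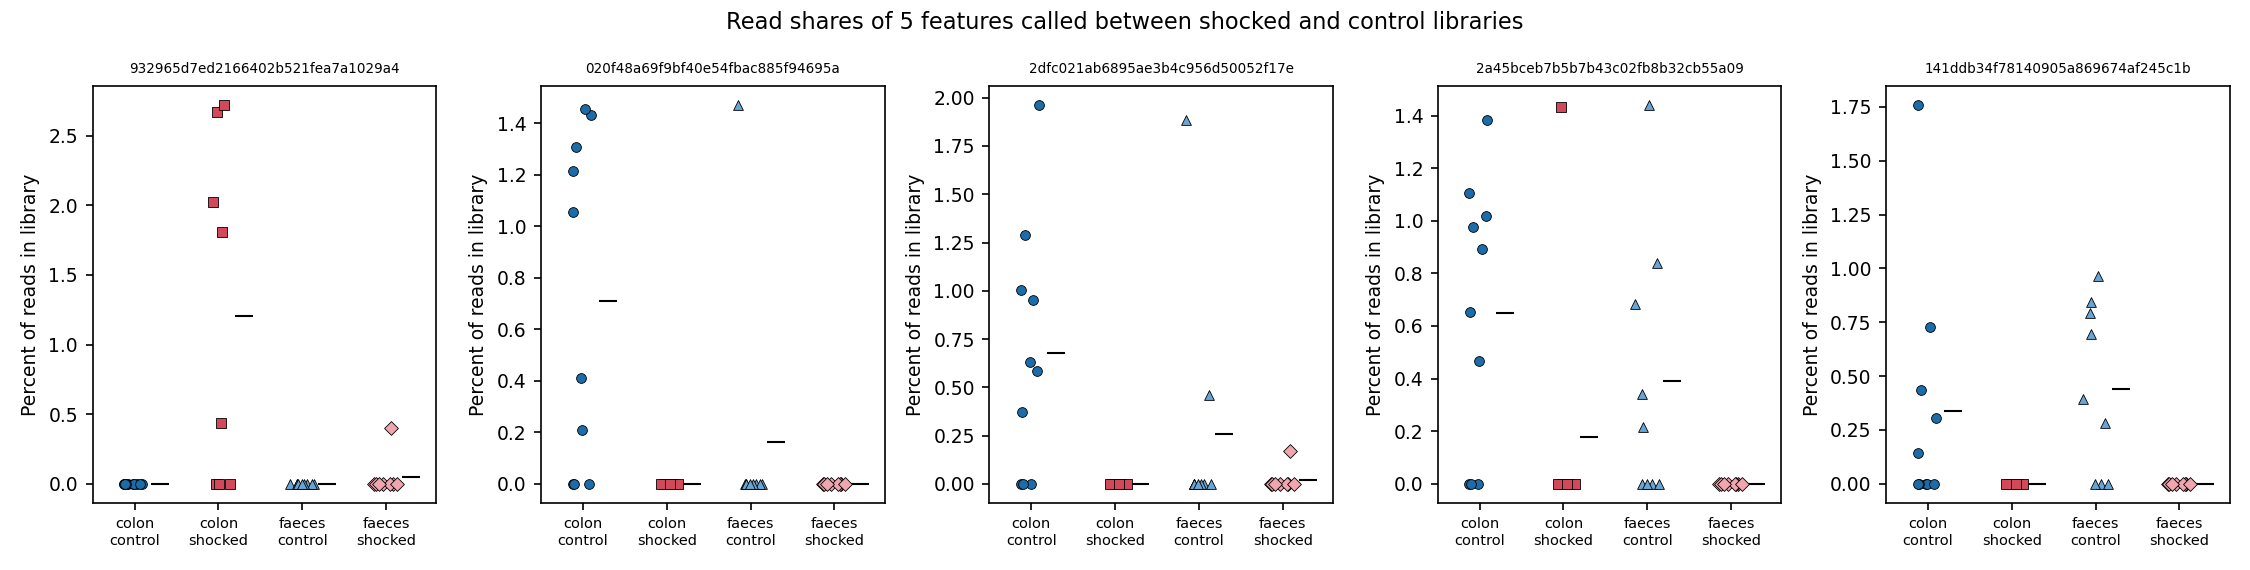
Percent of reads in each library for the 5 features named for the footshock comparisons, by group; points are libraries and short lines the group means. The first feature reaches 2.72% in shocked colon and is at 0 in all control colon libraries, and the others are at 0 in all 8 libraries of the shocked group in which they fell.

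A further comparison tested whether the response to footshock differed between colon and faeces. The diversity responses had opposite signs: at 1000 reads, shocked minus control was -29.2 features in colon and 17.4 in faeces. The difference of the 2 responses was 46.5 features (two-sided permutation of treatment within compartment, p = 0.0146) and 0.541 units of the Shannon index (permutation p = 0.0187), each with an adjusted p of 0.075 over the 8 diversity comparisons. Neither difference passes the threshold after adjustment. For single features, edgeR called 0 of 127 with a response that differed between compartments, where 13 had an unadjusted p under 0.05; DESeq2 called 2 and limma on centred log-ratios 0. The interaction accounted for 1.45% of the variation in Bray-Curtis distance (permutation p = 0.892).

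The fourth comparison set colon against faeces over both treatments. Of 127 features tested, 10 were higher in colon and 8 higher in faeces (edgeR, adjusted p under 0.05). The count of 18 was 21 by DESeq2, 29 by limma on centred log-ratios, 11 with a filter at 50% of libraries and 11 without colon shocked 11 or colon shocked 12. It also rose with the library number as a block, a fit given below with the dependence on the processing. The 10 colon features together made up 29.9% ± 14.4 of colon reads (SD, n = 18) and 3.26% ± 1.44 of faecal reads (SD, n = 17). The 8 faecal features made up 23.1% ± 11.5 of faecal reads (SD, n = 17) and 7.82% ± 4.52 of colon reads (SD, n = 18). These sums describe features picked on the same libraries.

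Feature 1e5252f7f059d825508ebf3880dffd92 was read in 13 of 18 colon libraries at 3.41% ± 3.75 of reads (SD, n = 18) and in 0 of 17 faecal libraries, at least 107.4-fold higher in colon (edgeR adjusted p = 3.26e-09). Feature 12c4cf4a9b6a4541ef111f02191bae96 was read in 14 of 18 colon libraries at 2.42% ± 3.29 (SD, n = 18) and in 0 of 17 faecal libraries, at least 76.2-fold higher (edgeR adjusted p = 3.26e-09). Another of the 10 was also at 0 in every faecal library, at 2.22% ± 2.62 of colon reads (SD, n = 18). Their summed share was higher in colon libraries with fewer reads. The feature with the highest mean share in colon, at 6.91% ± 2.84 (SD, n = 18), was read in all 18 colon libraries and at 1.11% ± 0.620 in faeces (SD, n = 17), 6.23-fold higher in colon (edgeR adjusted p = 0.000159).

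Among features higher in faeces, the fitted change was largest for 0b7372a13611c07b69bf1a93545e738f, at 0.975% ± 1.69 of faecal reads (SD, n = 17) and 0.0610% ± 0.177 of colon reads (SD, n = 18; log2 fold change 4.01, edgeR adjusted p = 0.0194). Faeces control 2 held 5.64%, faeces shocked 16 held 4.83% and other faecal libraries at most 1.71%. The call was lost without faeces control 2 (log2 fold change 3.05, edgeR adjusted p = 0.0951) or faeces shocked 16 (3.56, adjusted p = 0.0590). Feature 078e0fd51a7d5e5b908328591895ba58 was at 0.0974% ± 0.244 in faeces (SD, n = 17) and 0.00241% ± 0.0102 in colon (SD, n = 18; log2 fold change 4.004, edgeR adjusted p = 0.0152). Its faecal mean was 0.0403% without faeces shocked 13, which held 1.01%, and its 7 colon reads were all in colon control 1. Floors of 3 reads averaged 0.170% over the colon libraries, above its faecal mean, so shallow colon libraries could not show it at that level. This call was lost without colon shocked 12 (log2 fold change 3.72, edgeR adjusted p = 0.0518). Both were read in 8 of 17 faecal libraries. Limma on centred log-ratios called neither (adjusted p = 0.209 and 0.593), and DESeq2 did not call the first (adjusted p = 0.0588). The feature with the highest mean share in faeces made up 9.14% ± 5.75 of faecal reads (SD, n = 17) and 4.11% ± 2.60 of colon reads (SD, n = 18), 2.23-fold higher in faeces (edgeR adjusted p = 0.04997). Next in mean share in faeces was a feature at 6.88% ± 3.50 there (SD, n = 17) and 2.38% ± 1.23 in colon (SD, n = 18), 2.90-fold higher in faeces (edgeR adjusted p = 0.00584).

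**Figure D3:**
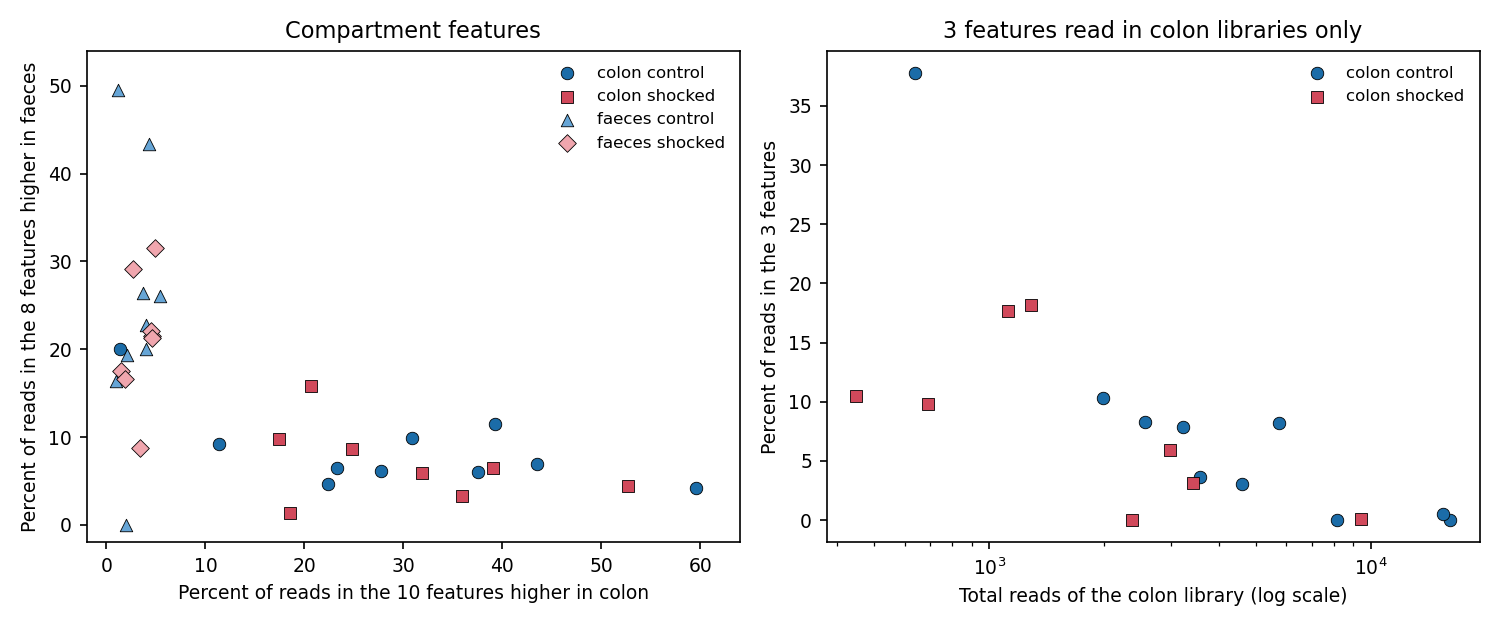
Left, percent of reads in the 10 features called higher in colon against percent in the 8 called higher in faeces, 1 point per library; right, summed percent of the 3 features read in colon only against total reads of each colon library on a log axis. Faecal libraries hold at most 5.44% of reads in the colon features, and colon control 8, with 638 reads, has the highest summed share of the 3, at 37.8%.

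Compartment accounted for 20.5% of the variation in Bray-Curtis distance (permutation p = 0.0001, the smallest that the permutations can give), and the spread of libraries around their compartment centres did not differ detectably (permutation p = 0.658). The mean distance was 0.584 ± 0.0907 between colon libraries (SD over 153 pairs), 0.562 ± 0.158 between faecal libraries (136 pairs) and 0.694 ± 0.111 between a colon and a faecal library (306 pairs). Colon and faeces did not separate in diversity: at 1000 reads, colon libraries held 94.6 ± 30.0 features (SD, n = 15) and faecal libraries 111.0 ± 24.0 (SD, n = 17; permutation p = 0.0942, adjusted p = 0.151), with a Shannon index of 3.79 ± 0.342 and 3.82 ± 0.309 (permutation p = 0.756). The difference in features passed the unadjusted threshold at 500 reads (15.01, permutation p = 0.047) and without both libraries numbered 1 (20.7, permutation p = 0.0388). The 2 libraries numbered 1 stood apart: colon control 1 lay among the faecal libraries and faeces control 1 away from both. Without them, a setting chosen after seeing the data, 33 features differed between compartments (22 higher in faeces, 11 higher in colon).

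**Figure D4:**
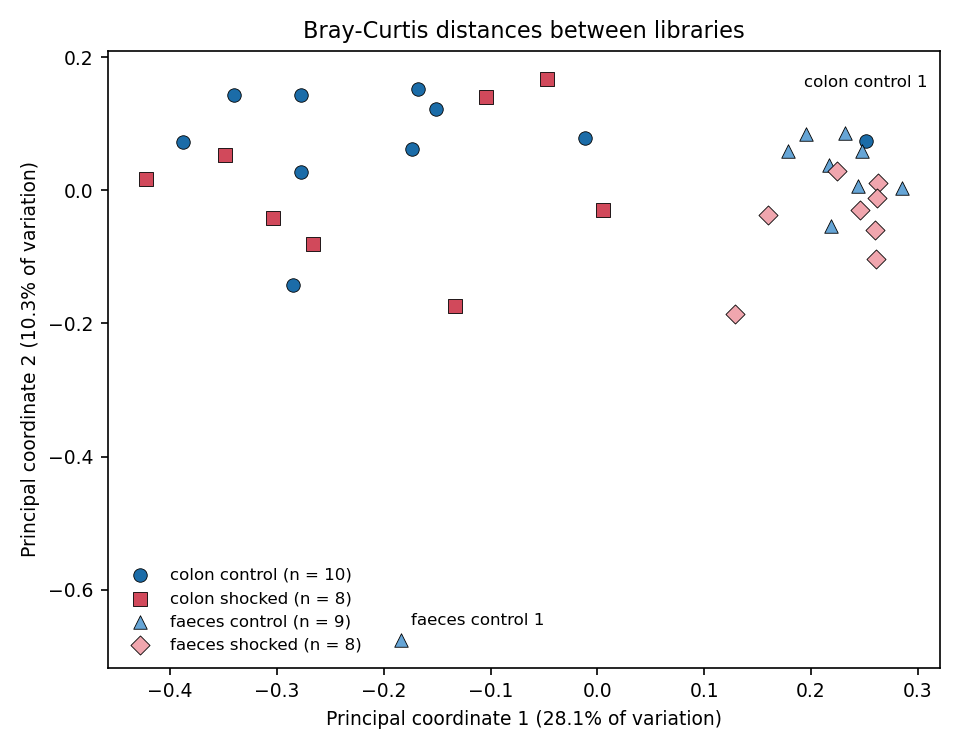
Principal coordinates of Bray-Curtis distances on read shares, with axis 1 holding 28.1% and axis 2 10.3% of the variation; points are libraries, coloured by group. Colon and faecal libraries lie apart on axis 1 except colon control 1, which lies among the faecal libraries, and faeces control 1, which lies within the colon range of axis 1 but alone at the low end of axis 2.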

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

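The tests of an exchange of libraries, of bacteria from elsewhere, of depth and of the relation between share and reads, and every value without the libraries numbered 1, were chosen after the results they bear on were seen. A gap of 1 library to the rest of its group was searched for in 32 combinations of a measure and a group, and 6 stood out. Chance alone marks about 1 in 20 if values are normally distributed. That was not checked, so the 6 cannot be set against this rate. Colon shocked 14 held 9418 reads where the other 7 shocked colon libraries held 448 to 3432. Features of no other library took 8.44% of reads in colon control 10 (95% exact interval 7.50% to 9.45%) and at most 3.37% in the other control colon libraries. In faeces shocked 13 such features took 11.8% of reads (95% exact interval 11.2% to 12.4%) and in the other shocked faeces at most 3.68%. The remaining 3 concern the libraries numbered 1. The footshock responses of colon and faeces were 0.541 units of the Shannon index (permutation p = 0.0187) and 46.5 features (permutation p = 0.0146) apart, which did not pass the threshold after adjustment over 8 comparisons (adjusted p = 0.075 for both).

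Both libraries numbered 1 lay outside their groups. Faeces control 1 had a mean Bray-Curtis distance of 0.961 to its group, where the others had 0.522 to 0.578. Features of no other library took 16.7% of its reads (95% exact interval 15.8% to 17.6%). Colon control 1 held 20.01% of its reads (95% exact interval 19.4% to 20.6%) in features higher in faeces. The other control colon libraries held at most 11.5% in them, and colon shocked 16 held 15.8%. A plain exchange of the pair is argued against, because faeces control 1 was at a mean distance of 0.924 from the colon libraries, whose own means reach 0.667. Colon control 1 may hold material of faecal composition: features called higher in colon without both libraries took 1.73% of its reads (95% exact interval 1.53% to 1.94%), against at most 6.17% in faecal libraries and at least 14.7% in other colon libraries. For faeces control 1 the source stays open: 43.3% of its reads (95% exact interval 42.1% to 44.5%) were in features of no other faecal library, which restates how it differs, and 26.6% (95% exact interval 25.5% to 27.7%) were in those of them that colon libraries hold, so bacteria from elsewhere, a library from outside these groups and an unusual animal cannot be told apart.

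Of the features higher in colon, 3 had no reads in any faecal library. Too little faecal depth is argued against, because the floor of 3 reads was at most 0.0638% of a faecal library. The lowest mean share of the 3 in colon was 2.22%, and the lowest mean less 2 standard errors 0.866%. Their summed share fell as colon libraries grew deeper (log2 share against log2 reads, Pearson r = -0.684, permutation p = 0.00155, adjusted p = 0.00465 over 6 relations; Spearman rho = -0.829, permutation p = 5.0e-05; n = 18), and it reached 37.8% in colon control 8 (95% exact interval 34.0% to 41.7%). The relation held without the 2 libraries farthest from the median depth (r = -0.609, permutation p = 0.0124), within controls (r = -0.771, permutation p = 0.00624; rho = -0.915, permutation p = 0.00047; n = 10) and had the same sign within shocked colon (r = -0.628, exact permutation p = 0.109; rho = -0.643, exact permutation p = 0.0962; n = 8). A candidate explanation is an input fixed per colon library and diluted by bacterial template, such as host DNA caught by the primers or reagent DNA, but bacteria attached to the gut wall and diluted by gut content would give the same relation, and the sequences that would tell these apart were not used here. The 3 features had 0 reads in colon control 1 (16155 reads in total), colon control 7 (8150) and colon shocked 13 (2362). Colon control 9 held 211 of its 2556 reads in them, so an input equal in every library is not borne out.

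Each feature called for footshock in colon was at 0 in 1 group. For the count of 8 in the main fit, regrouping is argued against as the source. Of 100 splits of the colon libraries, the real one included, 1 gave 8 or more calls, and the highest other gave 5. That count was unstable, at 2 to 15 with 1 library left out, and splits were not drawn for those fits. Lower depth of the shocked libraries stays open for 5 of the 8: with every library thinned to 1000 reads, and those below left out, 3 were still called (1 higher, 2 lower; edgeR adjusted p 0.0318 or less), while the other 5, the feature also called in faeces among them, went from log2 fold changes of -7.02 to -6.52 to changes of -5.18 to -4.21 (edgeR adjusted p = 0.0596). With full counts and only the libraries under 1000 reads left out, the 5 were at -7.37 to -6.95 (edgeR adjusted p = 0.0891), so those calls ended without a smaller fitted change, though fitted values of features at 0 are no bound. Simulated shocked libraries drawn from control profiles at the shocked depths left 0.348 ± 0.853 of 70 features of 5 or more control libraries unread on average (SD over 10000 draws), where 7 were unread. The draws were skewed and left up to 13 unread (one-sided simulation p = 0.0019). But this simulation takes the control profiles as known and settles nothing for the 5. Likeness of libraries with neighbouring numbers, as from shared housing, stays open. Consecutive numbers in a colon group had a mean distance of 0.576 and other pairs 0.575 (permutation p = 0.96). Bray-Curtis distance weighs features by their share, so this test says little on features as minor as those that fell. It also does not rule out cages or batches that follow the treatment, because all controls have lower numbers than all shocked animals. All 7 features that fell were read in each of colon control 2, 3 and 4, and none in colon control 8. Without control 2, 3 or 4 the calls numbered 4. A footshock effect on these features is also an open hypothesis (of the 8, DESeq2 called 3 and limma on centred log-ratios 1).

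In faeces, 5 of 100 splits gave 2 or more calls, the highest other split giving 6, so chance cannot be excluded. Between compartments, 1 of 100 splits gave 18 or more calls, that being the real one, and the highest other gave 4. Chance is thus argued against, but 100 splits can give no smaller share, and they did not keep libraries of the same number together. For the interaction the real split gave 0 calls, so all 100 splits gave as many, and the highest other gave 12.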

How the results depend on the processing

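Settings named as added were chosen after seeing the data; the cause of each change was not tested unless stated. Over 25 results, 132 of 177 alternatives kept direction and side of the threshold, 17 lost the threshold, 7 gained it and 21 moved a count by over 1.5 times; with 1 library left out, 574 of 616 kept theirs. The 8 calls in colon became 3 with DESeq2, 2 with limma on centred log-ratios, 304 with no prevalence filter, 0 with a filter at 50% (3 of 40 at an unadjusted p under 0.05), 0 in 1 fit over all 4 groups (18 of 127 unadjusted), 3 after thinning (added), 3 without libraries under 1000 reads (added) and 0 by Fisher's exact test of detection (added; 13 of 95 unadjusted). Leaving out 1 library gave 2 to 15 calls: 4 without control 2, 3 or 4, 15 without shocked 11, 3 without shocked 16, and 2 without shocked 13, 15, 17 or 18. The 2 calls in faeces became 475 with no filter, 0 at 50% (1 of 66 unadjusted), 0 after thinning (added; 8 of 117 unadjusted), 0 by Fisher's exact test (added; 7 of 135 unadjusted) and 1 without both libraries numbered 1 (added), and 1 to 3 with 1 library left out (1 without control 1, 3, 7 or 8 or shocked 16). The 18 calls between compartments became 29 with limma, 414 with no filter, 11 at 50%, 33 without both libraries numbered 1 (added), and 11 to 23 with 1 library left out (11 without colon shocked 11 or 12). With no filter, 296 of the 304, 472 of the 475 and 396 of the 414 calls were features under the 25% filter, so those counts come from the rare features that the filter removes. The interaction, at 0 calls, had 2 with DESeq2 and 10 with no filter. The Shannon difference of responses fell to 0.417 at 500 reads (permutation p = 0.0716), and the compartment difference in features was 45.1 with no rarefaction (permutation p = 0.00578), 15.01 at 500 reads and 20.7 without both libraries numbered 1 (added). Treatment accounted for 10.5% (Jaccard at 1000 reads) and 8.45% (Aitchison on full counts) of variation in colon. In faeces it accounted for 7.64% (Aitchison on full counts) and 9.91% (without faeces control 1). Each had a permutation p under the threshold. With 1 library left out, the Shannon difference ranged from -0.350 to -0.174 in colon (p under the threshold without control 7), 0.228 to 0.363 in faeces (without control 3, 5 or 6 or shocked 12) and -0.0129 to 0.0755 between compartments, turning sign without colon control 7 or colon shocked 11. The difference in features ranged from -36.6 to -22.5 in colon (past the threshold without control 7 or 9 or shocked 14), 12.8 to 24.7 in faeces (without control 3) and 12.9 to 21.05 between compartments (without colon control 3 or faeces control 1). The variation by treatment ranged from 7.23% to 10.3% in colon (past it without shocked 11 or 16) and 7.04% to 9.91% in faeces (without control 1, 4 or 10). Colon and faecal libraries share numbers, and the main models did not take the numbers to pair animals. Of 17 same-number pairs, 9 correlated over 0.1 in their deviations from group means (range -0.245 to 0.532), a cut-off that was not planned. With the number as a block, 28 features differed between compartments, and 48 also without both libraries numbered 1 (added); the block changed no call of the other results it was run on. Named features under the filter in a setting, as with the filter at 50%, have no value there. Of 17 colon libraries, 6 were nearest to the faecal library of their own number and 5 correlated best with it. In the planned permutation test, same-number pairs were closer than shuffled ones (0.658 against 0.684, permutation p = 0.0445). Without number 1 (added), the distances were 0.640 against 0.682 (permutation p = 0.00045). The compartment tests without the block thus leave this likeness of same-number libraries out of account. The comparisons of genera, phyla, lists of bacteria and the ratio of Firmicutes to Bacteroidetes, with their alternatives, were not run, since the table names no taxa. Depth limits colon most: the floor of 3 reads is 0.670% of the shallowest library.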

Other observations

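The test of an abundant feature below was chosen after its values were seen. Feature f80166d86a7f15b69b6ac97505299c3a was among the 3 features read in all 35 libraries and ranked 4 by mean share over the table. It made up 2.12% ± 1.47 of reads in control colon (SD, n = 10) and 5.83% ± 4.06 in shocked colon (SD, n = 8), and 2.60% ± 2.61 in control faeces (SD, n = 9) and 7.31% ± 4.25 in shocked faeces (SD, n = 8). It passed the edgeR test in neither compartment (adjusted p = 0.676 in colon and 0.837 in faeces). As a hypothesis, footshock may raise this feature in both compartments. Log2 shares were centred per compartment and averaged per library number, so that libraries of 1 number count once whether or not they share an animal. Number 9 entered by its colon library alone. From the difference of mean log2 shares, shocked numbers were 3.12-fold higher than controls, with 8 of 8 above the control median. The exact permutation p was 0.00459 and the adjusted p 0.0459 over the 10 features with the highest mean share. The call is fragile: with 1 number left out at a time the fold was 2.74 to 3.56, and the adjusted p (exact permutation, 0.0169 to 0.102) was over 0.05 in 13 of 18 cases, staying under it only without number 9, 10, 11, 14 or 16. The other 9 abundant features had adjusted p of 0.661 or more. The result rests on a feature noticed first in these libraries and tested on them, and cages or batches that follow the treatment stay open.

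The summed share of the 3 features read in colon only did not separate the treatments, at 7.96% ± 11.2 of reads in control colon (SD, n = 10) and 8.16% ± 7.18 in shocked colon (SD, n = 8; exact permutation p = 0.679 on log2 shares). All 3 were read together in 12 of 18 colon libraries, and none of them in colon control 1, colon control 7 and colon shocked 13. Of the 51 features that faeces control 1 held and no other faecal library did, 14 had reads in colon libraries, and those 14 took 26.6% of its reads (95% exact interval 25.5% to 27.7%).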
